A study of Mus musculus with 9 samples.

How the data were processed

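RNA was taken from whole aortae of C57BL/6J mice that had been flash frozen, with RNeasy Plus kits. Libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and marks strand, and were read as single-end 75 nt reads on an Illumina NovaSeq. There were 9 libraries in 3 genotypes (Itga8-Cre, Myh11-Cre and Wild Type) with 3 mice each, and replicates were not pooled.

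The authors deposited a table of counts per gene, whose whole numbers were used for every test. They also deposited a table of signal, the counts divided by 1 size factor per sample, which was used only to check that these factors equal median-of-ratios factors of the counts. Per the labels, the genome was GRCm38.p6 and the tools named were fastp 0.20.0, STAR 2.7.0f, Subread 1.6.4, featureCounts, Salmon 0.13.1 and DESeq2, without their role or order. The annotation release and whether strand was used in counting are not given in the sources used here, so counts of overlapping genes are uncertain. Symbols were matched to GENCODE M21 for position and identifier, and 19245 of 19412 tested symbols had a single gene there. Total counts ran from 31419238 to 42497543 per library. Mitochondrial ribosomal RNA mt-Rnr2 took 12.34% to 18.18% of counts, Scd1 1.068% to 3.638% and Fasn 0.6633% to 3.363%.

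Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group were kept (19412 of 55453), TMM factors were computed, and a group-means model was fitted to all 9 libraries with robust quasi-likelihood dispersion (common biological coefficient of variation 0.294, median prior degrees of freedom 2.67). The 3 comparisons used the quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. DESeq2 1.42.0 (Wald test, default filtering) and limma 3.58.1 (voom) were run beside it. CPM used TMM-scaled library sizes. A gene was called separate when all 3 libraries of 1 group lay above all 3 of the other, which chance gives for 10% of genes. Ratios of single genes were compared by exact two-sided permutation tests, for which 3 against 3 mice cannot give a p under 0.1.

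Gene lists, comparisons, tests and the rule for named genes were fixed before the data were examined. There were 33 lists, of which 30 had 5 or more tested genes and were tested by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over these 30. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance 1 way and does not compare the list with other genes. For each list, members were also adjusted over the list alone. List results are given as median log2 fold change with the number of members higher or lower. A list score is the mean log2 CPM of its tested members.

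Named genes were the 2 targeted genes with the tested members of the locus and Y-linked lists, up to 12 called genes each way by size of change, up to 4 members of each list with the smallest adjusted p, and, where fewer than 10 genes were called, the 10 tested genes with the smallest p and a mean CPM of at least 1, leaving out unnamed gene models and antigen receptor segments. Genes outside this rule are said to be chosen after their values were seen. These are, in addition, the genes called by DESeq2 in both Cre lines, members of lists adjusted over the list alone, genes that mark tissue in single libraries, and genes named from the fit without Itga8-Cre 1 and Myh11-Cre 1.

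The pipeline was tested on simulated data with the group sizes and spread of these libraries, in which 100 genes each were changed 2-fold and 4-fold among 19412. The edgeR test recovered 33% to 44% of the 2-fold and 82% to 89% of the 4-fold changes, with 8 to 13 false calls per comparison. DESeq2 recovered 58% to 59% and 92% to 95%, with 52 to 64 false calls. A list of 30 genes raised 1.5-fold was called, with 0 of the 29 others. Genes were drawn independently of each other here, whereas the estimated correlation within real lists reached 0.975 for skeletal muscle markers. The simulation therefore cannot show how often camera with the preset correlation calls real lists falsely. For the overlap of both Cre lines, 20 simulations of unchanged groups against shared controls gave the level expected from shared libraries with no real effects. Genes were drawn independently there too.

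Alternatives planned in advance were other normalizations, filters and tools, fits on 2 groups only, mouse number as a block, the brown fat score as covariate, a test against a minimum change of 1.2-fold, and leaving out each library in turn. Mouse numbers were not taken as pairs in the main fit. Of 9 same-numbered pairs of libraries, 5 had a correlation of residuals above 0.1 (range 0.03 to 0.4, other pairs -0.35 to 0.24). Of the 9 libraries, 5 correlated best with their own number in both other groups. A factor shared by mouse number is therefore possible, though the labels name none. After the data were seen, 5 alternatives were added: smooth muscle and skeletal muscle scores as covariates, edgeR without robust moderation, and leaving out the 2 libraries poorest in muscle transcripts or the 3 richest in skeletal muscle transcripts.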

Results

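Messenger RNA was sequenced from whole aortae of 9 C57BL/6J mice, with 3 mice in each of 3 genotypes. Itga8-Cre mice carry Itga8-CreERT2, a tamoxifen-inducible Cre recombinase tied to Itga8, the gene of integrin alpha 8. Myh11-Cre mice carry Myh11-CreERT2, an inducible Cre tied to Myh11, the gene of smooth muscle myosin heavy chain. Wild Type mice were the controls, and the labels give no sex, age, tamoxifen treatment, copy number or batch. The series was made to compare the activity of the new Cre mouse with that of the Myh11-CreERT2 mouse. Total counts per library were 38493753, 31419238 and 32728042 in Itga8-Cre 1, 2 and 3, 42497543, 39802480 and 40339839 in Myh11-Cre 1, 2 and 3, and 33146553, 36503787 and 38210135 in Wild Type 1, 2 and 3. Of 55453 genes listed, 19412 were tested. Levels are given in CPM, counts scaled to a common library total, as mean ± SD of 3 mice.

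Transcripts of tissue around the vessel differed widely between mice of 1 genotype. Acta1, the actin of skeletal muscle, ranged from 4.57 CPM in Myh11-Cre 1 to 3640 CPM in Myh11-Cre 3. Ucp1, the uncoupling protein of brown fat, ranged from 1350 CPM in Itga8-Cre 2 to 4960 CPM in Itga8-Cre 1. Rag1, which cuts antigen receptor genes in developing lymphocytes, ranged from 0.443 CPM in Itga8-Cre 2 to 477 CPM in Itga8-Cre 3. Acta2, the actin of the smooth muscle of the vessel wall itself, ranged from 171 to 635 CPM within Myh11-Cre and from 323 to 1040 CPM within Wild Type. The common biological coefficient of variation was 0.294. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in each of the 9 libraries. Ddx3y ranged from 113 to 146 CPM and Uty from 46.5 to 54 CPM. The mean of Ddx3y was 126 ± 10.9 CPM in Itga8-Cre, 140 ± 5.37 CPM in Myh11-Cre and 124 ± 16.9 CPM in Wild Type. These like levels in every library argue against female mice in any group, and so against a difference in sex between the groups.

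Itga8 (ENSMUSG00000026768.10, chromosome 2, 12106632 to 12301922, GRCm38), the integrin gene of the new line, was lowest in Itga8-Cre aortae. It stood at 64.5 ± 11.3 CPM in Itga8-Cre and 273 ± 177 CPM in Wild Type, a 4.23-fold lower level, and all 3 Itga8-Cre libraries lay below all 3 Wild Type libraries. Single libraries were at 54.1, 76.5 and 62.9 CPM in Itga8-Cre, 72.4, 298 and 300 CPM in Myh11-Cre, and 475, 147 and 196 CPM in Wild Type. Itga8 fell by 2.08 on the log2 scale (SE 0.59) against Wild Type, with an adjusted p of 0.0139 adjusted over the list alone (the 2 targeted genes) and 0.699 over all genes tested. DESeq2 gave an adjusted p of 0.0482 over all genes. The list-alone call ended without Itga8-Cre 1 (log2 fold change -1.97, adjusted p = 0.0575) or Wild Type 1 (-1.42, adjusted p = 0.0593).

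Set against Acta2, Itga8 was also lower in Itga8-Cre. The ratio of Itga8 to Acta2 was 0.234 ± 0.0234 (SD, n = 3) in Itga8-Cre, 0.465 ± 0.04 in Myh11-Cre and 0.479 ± 0.0382 in Wild Type. It was 2.05-fold lower in Itga8-Cre than in Wild Type, more than the spread between mice, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 mice allow. Against each of the 36 smooth muscle contractile genes, the log2 ratio of Itga8 was lower in Itga8-Cre than in Wild Type, by a median of -1.49 (range -2.48 to -1.01), and the groups were separate for 35 of the 36 genes. These ratios share the same Itga8 values, so they are not separate evidence. The ratio of Myh11 to Acta2 was 2.46 ± 0.388 in Itga8-Cre and 2.43 ± 1.02 in Wild Type. The antisense gene E030013I19Rik, chosen after its values were seen, had a ratio to Acta2 of 0.0158 ± 0.00192 in Itga8-Cre, 0.019 ± 0.00278 in Myh11-Cre and 0.025 ± 0.00203 in Wild Type, so it was lower in both Cre lines than in Wild Type and not separate between them (exact permutation p = 0.2). It overlaps Itga8 on the opposite strand, so their reads cannot be told apart if strand was not used in counting.

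Myh11 (ENSMUSG00000018830.10, chromosome 16, 14194535 to 14291372) was 1.71-fold lower in Itga8-Cre, at 670 ± 67 CPM against 1150 ± 201 CPM in Wild Type. It fell by 0.77 on the log2 scale (SE 0.32), with an adjusted p of 0.0385 adjusted over the list alone, 0.699 over all genes, and 0.428 by DESeq2. That call ended without Itga8-Cre 1 (-0.72, adjusted p = 0.0919), Itga8-Cre 2 (-0.86, 0.0523), Itga8-Cre 3 (-0.75, 0.0901), Wild Type 1 (-0.64, 0.118) or Wild Type 2 (-0.82, 0.062), and in a test against a minimum change of 1.2-fold. In Myh11-Cre, Myh11 was at 873 ± 359 CPM and Itga8 at 223 ± 131 CPM, with log2 fold changes against Wild Type of -0.39 and -0.29 that did not pass the test. Itga8 turned to 0.39 without Wild Type 1 and to 0.13 without Myh11-Cre 1, and did not pass there either. Without Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3, the libraries richest in skeletal muscle transcripts, Myh11 and Itga8 became -1.32 and -1.91. This setting was chosen after the data were seen, and it leaves 1 Myh11-Cre library, which is assumed to vary like the other groups.

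**Figure D1:**
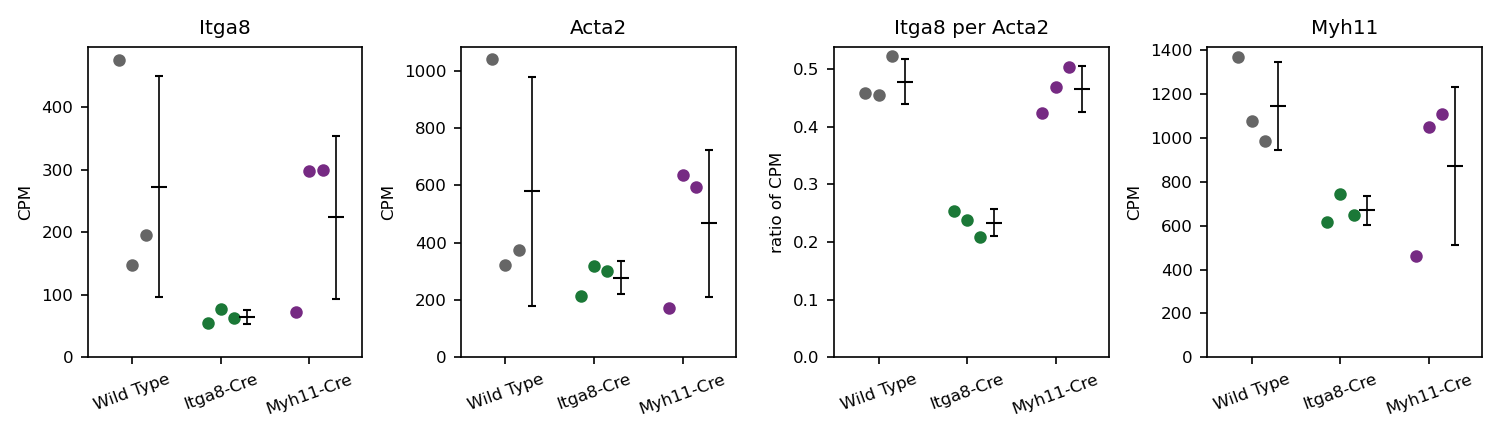
CPM of Itga8, Acta2 and Myh11 and the ratio of Itga8 to Acta2 CPM in each library, by genotype; points are single mice, and the dash and bar are the mean and SD of 3 mice. Itga8 lay between 54.1 and 76.5 CPM in the 3 Itga8-Cre libraries and between 147 and 475 CPM in the 3 Wild Type libraries.

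The comparison of Itga8-Cre with Wild Type asked what else differed in aortae that carry the new Cre. Of the 10 genes with the smallest p, all but Fermt3 were lower in Itga8-Cre. Irs2, an adaptor protein of the insulin receptor, was at 48 ± 6.36 CPM in Itga8-Cre and 124 ± 20.2 CPM in Wild Type, a 2.58-fold lower level. Impdh1, an enzyme of guanine nucleotide synthesis, was at 83 ± 10 against 208 ± 37 CPM. Spry4, an inhibitor of receptor tyrosine kinase signalling, was at 9.45 ± 1.47 against 23.9 ± 5.57 CPM. Irs1, a second insulin receptor adaptor, was at 66.4 ± 7.78 against 110 ± 17.6 CPM.

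None of these passed over all genes in edgeR. Of 19412 genes, edgeR called 0 (smallest adjusted p 0.494) and limma voom called 0. At an unadjusted p under 0.05 there were 1316 genes, 770 higher and 546 lower, where 971 are given by chance. Other splits of the same 6 libraries gave up to 2262 such genes. DESeq2 called 30 genes, 4 higher and 26 lower, with adjusted p values of 1.32e-08 for Irs2, 3.99e-08 for Impdh1, 4.48e-07 for Spry4 and 0.00261 for Irs1. In the simulated data 52 to 64 of the 204 to 215 DESeq2 calls per comparison were false. That is more than the threshold of 0.05 is meant to allow. A DESeq2 call alone is therefore weak evidence, here and below. The simulated data held genes changed 2-fold and 4-fold. Their number of false calls therefore cannot be set against the 30 called here or the 19 called between the Cre lines. Other genes among the 10 smallest p values had log2 fold changes of -1.2 for Dcun1d3, -0.88 for the exchange factor Net1, -0.6 for Lonrf1, -0.92 for Mmd2, -0.82 for the estrogen receptor Esr1 and 0.73 for the blood cell protein Fermt3. All 10 were separate between the 3 Itga8-Cre and 3 Wild Type libraries. Over all genes, 2160 (11.1%) were separate in this way, where 10% are given by chance.

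Lists of markers described the groups of genes. Macrophage and leukocyte markers rose as a list in Itga8-Cre (median log2 fold change 0.58, 21 of 24 higher, camera adjusted p = 4.97e-10, and adjusted p = 0.521 with an estimated correlation), with Lyz2 at 530 ± 198 against 209 ± 46.2 CPM and Cd68 at 13.6 ± 5.61 against 6.53 ± 0.479 CPM. Lymphocyte markers rose (0.71, 21 of 21 higher, adjusted p = 2.62e-08, and adjusted p = 0.521 with an estimated correlation), with log2 fold changes of 0.91 for Trac and 0.89 for Cd3g. Mesothelial and epithelial markers rose (1.31, 12 of 12 higher, adjusted p = 1.45e-08, and adjusted p = 0.521 with an estimated correlation), with 1.24 for Msln and 1.75 for Krt19. Smooth muscle contractile genes fell as a list (-0.44, 28 of 36 lower, adjusted p = 1.31e-07, and adjusted p = 0.723 with an estimated correlation), with values of -0.57 for Cspg4, -0.3 for Notch3 and -0.52 for Smtn. Immediate early genes fell (-0.27, 19 of 25 lower, adjusted p = 1.76e-05, and adjusted p = 0.521 with an estimated correlation), with -1.15 for Ccn1, -0.98 for Egr1 and -0.7 for Jun. Nerve and glial markers fell (-0.34, 18 of 21 lower, adjusted p = 0.000485, and adjusted p = 0.521 with an estimated correlation). These 6 calls stood without each of the 9 libraries in turn.

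Further list calls depended on single libraries. Cell cycle genes rose (0.82, 28 of 28 higher, adjusted p = 9.82e-07, and adjusted p = 0.851 with an estimated correlation), but not without Itga8-Cre 3 (0.978), the library with the most Rag1. Interferon response genes rose (0.16, 24 of 30 higher, adjusted p = 0.00951, and adjusted p = 0.851 with an estimated correlation), but not without Itga8-Cre 2 or Wild Type 2 (up to 0.537). Circadian clock genes fell (-0.08, 15 of 18 lower, adjusted p = 0.0102, and adjusted p = 0.521 with an estimated correlation), but not without Itga8-Cre 2 (0.506). Fat cell markers fell (-0.21, adjusted p = 0.0102, and adjusted p = 0.918 with an estimated correlation), but not without Itga8-Cre 2, Itga8-Cre 3 or Wild Type 1 (up to 0.917). The lists of TGF-beta and BMP response genes (-0.15, adjusted p = 0.0338, and adjusted p = 0.851 with an estimated correlation), extracellular matrix genes (-0.09, adjusted p = 0.0437, and adjusted p = 0.918 with an estimated correlation) and endothelial markers (-0.05, adjusted p = 0.0483, and adjusted p = 0.87 with an estimated correlation) fell, and all 3 calls ended without Itga8-Cre 3 or Wild Type 1 (up to 0.668, 0.898 and 0.898). The call on matrix genes ended also without Myh11-Cre 2, and that on endothelial markers without Myh11-Cre 2 or Myh11-Cre 3. With the brown fat score as covariate, matrix genes and endothelial markers did not pass either (0.0832 and 0.0505). Without Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3 together, a setting chosen after the data were seen, cell cycle genes (0.995) and matrix genes (0.711) turned direction and did not pass.

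With an estimated correlation between genes, 0 of these 13 lists were called, and the smallest adjusted p with an estimated correlation was 0.521. The other 17 lists did not pass (adjusted p from 0.0693 to 0.911): neighbours of Itga8 and of Myh11, modulated smooth muscle genes, integrin subunits, myosin chains, the serum response factor and myocardin family, estrogen receptor, p53, heat shock and hypoxia response genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, and markers of brown fat, fibroblasts, skeletal muscle, cardiac muscle and red blood cells. Among the lists not passing, the median and mean of brown fat markers were -0.08 and 0.15 with a test direction of down, and those of myosin chains were 0.17 and 0.22, also with a test direction of down. Besides the targeted genes, single members passed in 3 lists when adjusted over the list alone, and 0 members of any list passed over all genes. Esr1 fell (adjusted p = 0.00779 over the list alone), at 41.8 ± 8.49 against 73.9 ± 7.62 CPM. Myh10, the non-muscle myosin heavy chain IIB, fell by 0.69 (SE 0.16), with 0.0495 over the modulated smooth muscle genes and 0.0452 over the myosin chains. The first Myh10 call ended without any 1 library except Myh11-Cre 1 and Myh11-Cre 2 (adjusted p up to 0.182). The second ended without Itga8-Cre 1 or 3, Myh11-Cre 2 or any Wild Type library (up to 0.222).

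**Figure D2:**
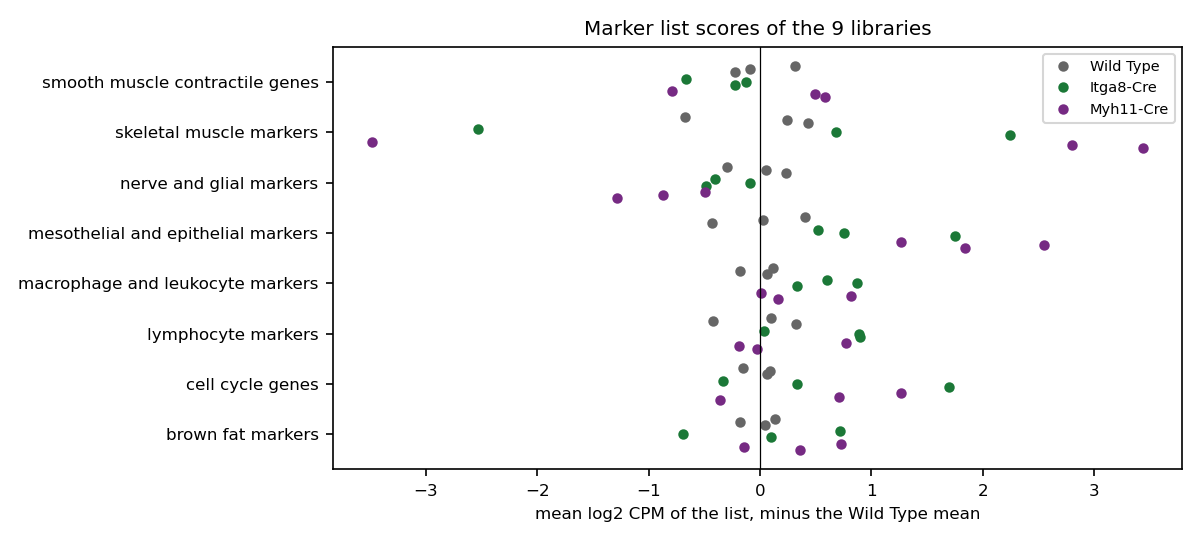
Mean log2 CPM of 8 marker lists in each library, minus the mean of the 3 Wild Type libraries (horizontal axis); points are single mice, coloured by genotype. Skeletal muscle markers spread most, from a mean log2 CPM of 2.78 in Myh11-Cre 1 to 9.71 in Myh11-Cre 3 before the Wild Type mean was taken off.

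The comparison of Myh11-Cre with Wild Type described aortae that carry the widely used Cre. Hccs (ENSMUSG00000031352.10, chromosome X, 169250193 to 169320372), the enzyme that attaches heme to cytochrome c, was at 79.4 ± 10.8 CPM in Myh11-Cre and 29.5 ± 2.2 CPM in Wild Type, a 2.69-fold higher level. Fopnl (chromosome 16, 14299244 to 14317405), a centrosome gene next to Myh11, was at 45.9 ± 0.45 against 27.2 ± 1.79 CPM and was 1.68-fold higher. Nefm, a neurofilament subunit of nerve cells, was at 2.38 ± 1.28 against 12.4 ± 5.96 CPM. Msln, a surface protein of mesothelium, was at 32.5 ± 11.8 against 6.66 ± 2.54 CPM.

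Over all 19412 genes, edgeR called 0 (smallest adjusted p 0.218) and limma voom called 0. At an unadjusted p under 0.05 there were 3187 genes, 1346 higher and 1841 lower, and 5056 genes (26%) were separate between the groups, where 971 genes and 10% are given by chance. Other splits of the same 6 libraries gave up to 2147 genes at that p. DESeq2 called 828 genes, 251 higher and 577 lower, among them Hccs (adjusted p = 1.72e-09) and Fopnl (2.05e-05). Hccs was the single gene called by edgeR with no filter on low counts, with mouse number as a block, and with the brown fat score as covariate. Without Itga8-Cre 1 and Myh11-Cre 1, the libraries poorest in muscle transcripts, edgeR called 284 genes, 249 higher and 35 lower, a setting chosen after the data were seen. These included, all as higher, 8 of 21 skeletal muscle markers, 5 of 36 contractile genes, 4 of 21 myosin chains and 3 of 12 mesothelial markers. Skeletal muscle scores of Myh11-Cre 2 and 3, which stayed, were 9.07 and 9.71, against 5.59 to 6.7 in Wild Type. Since libraries were left out by their muscle transcripts, the calls on muscle genes followed from that choice. Single genes with small p included Pgam2 (log2 fold change 2.24) and Eno3 (2.31), beside Tmprss2 (4.52) and Htr3a (-2.24).

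Fopnl was the neighbour of Myh11 that rose when adjusted over the list alone (log2 fold change 0.75, SE 0.1, adjusted p = 0.000651), and the call stood without each of the 9 libraries in turn. Of the other tested neighbours, Nde1 was at 0.27 and Abcc1 at -0.1. Gene 2900011O08Rik, at 1.21 ± 0.632 against 3.59 ± 1.64 CPM, had -1.57 and was called by DESeq2 (adjusted p = 0.0319). Among the 10 tested genes on either side of Myh11, edgeR called 0, 4 of 20 had an unadjusted p under 0.05, and DESeq2 called 2 (Fisher's exact test, two-sided p = 0.211). In Itga8-Cre against Wild Type, edgeR and DESeq2 called 0 of the 20 genes around Itga8, and 1 had an unadjusted p under 0.05.

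Some genes at the end of the X chromosome had higher values in Myh11-Cre, and others among them did not. Tlr7, a receptor for single-stranded RNA, was at 15.2 ± 3.13 against 6.24 ± 0.736 CPM (2.43-fold higher, DESeq2 adjusted p = 2.98e-05). Arhgap6, which overlaps Hccs on the opposite strand, was at 14.2 ± 3.15 against 7.98 ± 0.449 CPM (DESeq2 adjusted p = 0.00603), and whether strand was used in counting is not given in the sources used here. Between them, Msl3 was at 29.7 ± 1.82 against 27.7 ± 2.01 CPM, with a log2 fold change of 0.1 (SE 0.09). Prps2 had 1.03 (SE 0.32, DESeq2 adjusted p = 0.0435), Tlr8 1.17 (SE 0.49) and Frmpd4 -1.35 (SE 0.59), and the flanking genes Tmsb4x and Mid1 had 0.03 (SE 0.22) and 0.2 (SE 0.24). Apart from Hccs and Tlr7, these genes were chosen after their values were seen. None of these X-linked genes passed over all genes in edgeR.

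**Figure D3:**
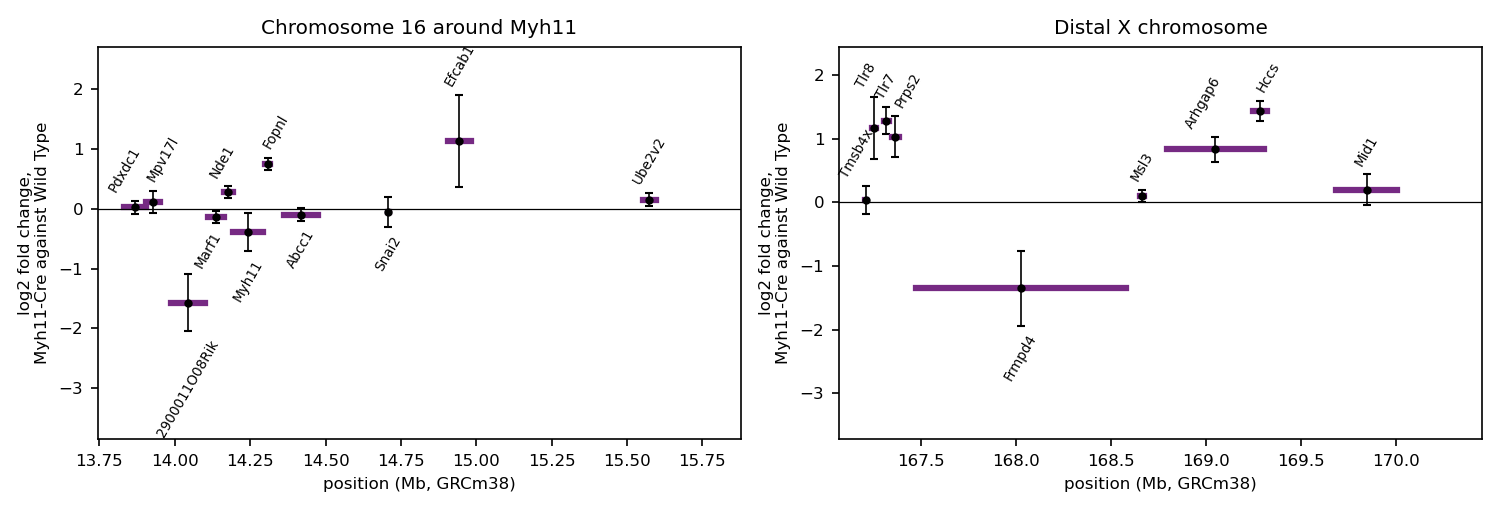
Log2 fold change of tested genes in Myh11-Cre against Wild Type by position (Mb, GRCm38) around Myh11 on chromosome 16 and at the end of the X chromosome; thick lines span each gene, and bars are 1 SE either side. Fopnl (0.75) and Hccs (1.43) lie well above 0, and Msl3 (0.1) does not.

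Irs2, Impdh1 and Spry4 were lower in Myh11-Cre too, at 54.8 ± 10.1, 86 ± 15.8 and 10.5 ± 1.25 CPM, with DESeq2 adjusted p values of 9.55e-06, 8.19e-07 and 5.21e-05. Mmd2 was at 6.68 ± 0.239 against 15.9 ± 2.55 CPM, Islr2 at 3.05 ± 0.076 against 8.03 ± 1.51 CPM, and Ncald, a neuronal calcium sensor, at 18 ± 3.29 against 39.5 ± 6.77 CPM. In edgeR none of these 6 passed over all genes.

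Nerve and glial markers fell as a list in Myh11-Cre (median -0.54, 16 of 21 lower, camera adjusted p = 4.42e-08, and adjusted p = 0.436 with an estimated correlation). Of the 21 members, 11 fell when adjusted over the list alone, and 0 passed over all genes. The 11 included the noradrenaline synthesis genes Th (-1.97) and Dbh (-1.91), the neurofilament genes Nefm (-2.38) and Nefl (-1.92), and the secretory granule gene Chgb (-2.12). All 11 member calls ended without Myh11-Cre 2, Wild Type 2 or Wild Type 3 (adjusted p of Th up to 0.0636 and of Chga up to 0.147). The calls on Cdh19, Chga and Ncam1 ended also without Myh11-Cre 3, on Chga also without Itga8-Cre 1, and on Ncam1 also without Myh11-Cre 1 or Wild Type 1.

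Mesothelial and epithelial markers rose as a list (median 2.2, 12 of 12 higher, camera adjusted p = 3.54e-14, and adjusted p = 0.375 with an estimated correlation), and 10 of 12 members rose when adjusted over the list alone. Msln (2.29), Krt19 (2.71), Krt7 (2.27), Muc16 (1.57) and Upk1b (1.61) stood without each of the 9 libraries. The calls on Krt8, Epcam, Cdh1, Upk3b and Lrrn4 ended without Myh11-Cre 2, Wild Type 2 or Wild Type 3 (adjusted p of Lrrn4 up to 0.114). Those on Krt8, Epcam and Cdh1 ended also without Wild Type 1, and on Krt8 and Cdh1 without Myh11-Cre 3.

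Nuclear oxidative phosphorylation genes rose (0.37, 30 of 30 higher, camera adjusted p = 1.3e-06, and adjusted p = 0.801 with an estimated correlation), with Atp5c1 at 444 ± 36.2 against 318 ± 5.23 CPM. Their score was highest in Myh11-Cre 1 (9) and Itga8-Cre 1 (8.99) and lowest in Itga8-Cre 2 (8.08). The brown fat score had the same order there (7.88, 7.87 and 6.46). With the brown fat score as covariate the camera call stood (adjusted p = 0.000125). Cardiac muscle markers rose (1.25, 14 of 14 higher, adjusted p = 3.95e-05, and adjusted p = 0.801 with an estimated correlation), with Tcap at 1.95, and 7 of the 14 genes are in another list. Hypoxia response genes rose (0.42, 15 of 19 higher, adjusted p = 0.00365, and adjusted p = 0.774 with an estimated correlation), with 1.01 for Egln3. These 3 list calls, and those on nerve and mesothelial markers, stood without each of the 9 libraries in turn. Without Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3 together, cardiac muscle markers turned direction. This setting was chosen after the data were seen and leaves 1 Myh11-Cre library.

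The remaining list calls in Myh11-Cre against Wild Type each ended without at least 1 library. Skeletal muscle markers rose (2.54, 21 of 21 higher, adjusted p = 0.000229, and adjusted p = 0.801 with an estimated correlation), but not without Myh11-Cre 3 (0.118). Cell cycle genes rose (0.72, 28 of 28 higher, adjusted p = 0.000474, and adjusted p = 0.801 with an estimated correlation), but not without Myh11-Cre 1 (0.332). Their score was 3.93, 3.37 and 2.3 in Myh11-Cre 1, 2 and 3, where Rag1 had 9999, 9568 and 1713 counts. Heat shock and unfolded protein genes rose (0.16, 25 of 30 higher, adjusted p = 0.00365, and adjusted p = 0.801 with an estimated correlation), but not without Wild Type 2 (0.0709). Their member Herpud1 rose when adjusted over the list alone, at 166 ± 10.4 against 96 ± 10.4 CPM (adjusted p = 0.0123), but not without Myh11-Cre 3, Wild Type 1 or Wild Type 3 (up to 0.079). Macrophage and leukocyte markers (0.36, adjusted p = 0.00365, and adjusted p = 0.801 with an estimated correlation) and red blood cell genes (1.15, adjusted p = 0.0251, and adjusted p = 0.801 with an estimated correlation) rose, but not without Myh11-Cre 2 or Wild Type 2 (up to 0.283 and 0.458). Fibroblast and adventitial markers rose (0.32, adjusted p = 0.00582, and adjusted p = 0.801 with an estimated correlation), but not without Myh11-Cre 2, Myh11-Cre 3 or Wild Type 2 (up to 0.238). Myosin chains rose (0.84, adjusted p = 0.0236, and adjusted p = 0.801 with an estimated correlation), but not without Myh11-Cre 2, Myh11-Cre 3, Wild Type 1 or Wild Type 3 (up to 0.274). Without Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3 together, skeletal muscle, myosin, fibroblast, macrophage and red blood cell lists turned to lower. That fit leaves only Myh11-Cre 1, whose skeletal muscle score (2.78) was below those of Wild Type (5.59, 6.51 and 6.7). The libraries left out were picked on skeletal muscle transcripts, so the turn of the muscle lists followed from that choice.

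Immediate early genes fell (-0.17, 18 of 25 lower, adjusted p = 0.0476, and adjusted p = 0.801 with an estimated correlation), but not without any 1 of the Itga8-Cre libraries, Myh11-Cre 1, Wild Type 1 or Wild Type 3 (up to 0.576). With the brown fat score as covariate, immediate early genes (0.126) and red blood cell genes (0.088) did not pass. With an estimated correlation, 0 of the 13 lists were called, and the smallest adjusted p with an estimated correlation was 0.375. The other 17 lists did not pass (adjusted p from 0.181 to 0.986). Smooth muscle contractile genes were among these, with a median of -0.03 and a mean of 0.2, 18 of 36 higher and an adjusted p of 0.986. Without Myh11-Cre 1 they passed as higher (0.000513). Without Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3 together, which leaves 1 Myh11-Cre library, their test direction was down. Notch3, at 82 ± 1.76 against 106 ± 6.7 CPM, was called lower by DESeq2 (adjusted p = 0.0112).

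Adjusted over the list alone, 2 further genes passed. Itgb8, an integrin beta subunit, fell to 13 ± 0.975 from 19.9 ± 1.13 CPM (adjusted p = 0.0177), but not without Myh11-Cre 1, Myh11-Cre 3, Wild Type 2 or Wild Type 3 (up to 0.105). Myh10 fell by 0.68 (SE 0.16, adjusted p = 0.0479 over the myosin chains), but not without Itga8-Cre 1, Itga8-Cre 3, Myh11-Cre 2 or any Wild Type library (up to 0.119).

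**Figure D4:**
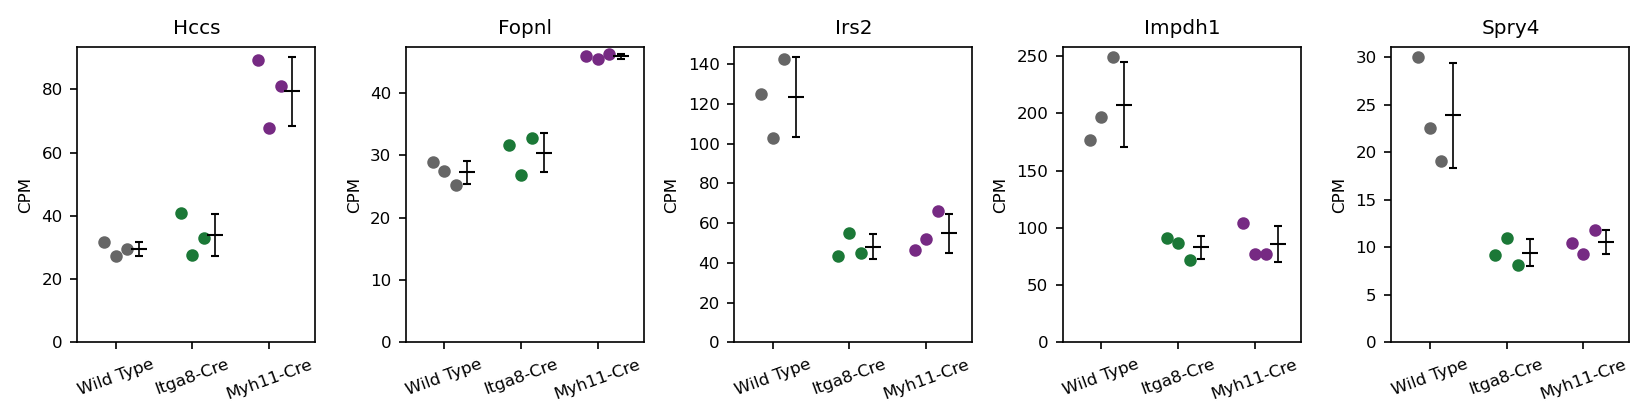
CPM of Hccs, Fopnl, Irs2, Impdh1 and Spry4 in each library, by genotype; points are single mice, and the dash and bar are the mean and SD of 3 mice. The 3 Myh11-Cre libraries lay above all others for Hccs and Fopnl, and the 3 Wild Type libraries lay above all others for Irs2, Impdh1 and Spry4.

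The direct comparison of Itga8-Cre with Myh11-Cre set the new line against the widely used one. Itga8 was lower in Itga8-Cre by -1.79 on the log2 scale (SE 0.58), and passed when adjusted over the list alone (adjusted p = 0.0283) but not over all genes (0.521) or by DESeq2 (0.134). Fopnl fell by 0.59 (SE 0.1), from 45.9 ± 0.45 CPM in Myh11-Cre to 30.4 ± 3.19 CPM in Itga8-Cre, with an adjusted p of 0.00367 over the list alone, and stood without each of the 9 libraries. Hccs was at 33.9 ± 6.68 against 79.4 ± 10.8 CPM, a 2.34-fold lower level (DESeq2 adjusted p = 1.14e-06). Smooth muscle contractile genes fell as a list in Itga8-Cre (median -0.51, 35 of 36 lower, camera adjusted p = 8.42e-06, and adjusted p = 0.612 with an estimated correlation), with values of -1.25 for Actg2, -1.14 for Hspb6 and -0.8 for Myl9. Skeletal muscle markers moved with them (median -1.48, 21 of 21 lower). The contractile list turned to higher without Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3, which leaves only the Myh11-Cre library poorest in skeletal muscle markers.

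The Itga8 call ended without Itga8-Cre 1 (-1.68, adjusted p = 0.099), Itga8-Cre 2 (-1.95, 0.0582), Itga8-Cre 3 (-1.78, 0.0776), Myh11-Cre 2 (-1.53, 0.0866) or Myh11-Cre 3 (-1.52, 0.0878), with no filter on low counts, and with mouse number as a block. It ended also with the skeletal muscle score as covariate (-1.39). With the smooth muscle score the call stood, but the log2 fold change shrank to -0.85 (SE 0.28, adjusted p = 0.0316 over the list alone). Without Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3, which leaves 1 Myh11-Cre library, it was -0.15. These settings were chosen after the data were seen. Myh11 had a log2 fold change of -0.38 that did not pass, but fell by 0.71 without Myh11-Cre 1 (adjusted p = 0.00764 over the list alone). Its log2 fold change turned to 0.09 with the smooth muscle score as covariate, and to 0.56 without Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3. Set against the 36 contractile genes, the log2 ratio of Itga8 was lower in Itga8-Cre than in Myh11-Cre for 36 of 36, by a median of -1.13, and the groups were separate for 24 of 36.

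Snx29, a further gene near Myh11, was higher in Itga8-Cre, at 30.3 ± 6.1 against 21 ± 1.33 CPM. It rose by 0.53 (SE 0.14) when adjusted over the list alone (adjusted p = 0.0374), but 8 of the 9 fits without 1 library did not call it (adjusted p up to 0.157). The exception was the fit without Itga8-Cre 1. Over all genes, edgeR called 0 (smallest adjusted p 0.521), limma voom called 0, and DESeq2 called 19, 13 higher and 6 lower. At an unadjusted p under 0.05 there were 1840 genes, 1484 higher and 356 lower, where 971 are given by chance, and 2469 genes (12.7%) were separate between the groups, where 10% are given by chance. Other splits of the same 6 libraries gave up to 3002 genes at that p. With the brown fat score as covariate edgeR called 1 gene, Hccs. Other genes among the 10 smallest p values had log2 fold changes of -0.55 for Syde2, 1.46 for BE692007, 1.07 for Rab37, 1.01 for Shank1, 0.69 for Gmip, 0.81 for Arhgap22, 0.86 for Arhgap9 and 0.59 for H2-T24. Of these 8, H2-T24 was not called by DESeq2.

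Among the other lists, fibroblast and adventitial markers fell (-0.38, 19 of 20 lower, adjusted p = 1.89e-05, and adjusted p = 0.612 with an estimated correlation), with -0.64 for Gsn. Mesothelial and epithelial markers fell (-0.75, 11 of 12 lower, adjusted p = 8.29e-05, and adjusted p = 0.612 with an estimated correlation), with -1.05 for Msln. Heat shock and unfolded protein genes fell (-0.14, 27 of 30 lower, adjusted p = 0.000421, and adjusted p = 0.612 with an estimated correlation), with -0.83 for Hspa1a. Circadian clock genes fell (-0.28, 16 of 18 lower, adjusted p = 0.000565, and adjusted p = 0.612 with an estimated correlation), with -0.66 for Nfil3. Nerve and glial markers rose (0.31, 16 of 21 higher, adjusted p = 0.000421, and adjusted p = 0.612 with an estimated correlation), with 1.53 for Nefm and 1.26 for Th. These 5 calls and that on contractile genes stood without each of the 9 libraries. Without Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3 together, the contractile genes and fibroblast markers turned to higher in Itga8-Cre. Nerve and glial markers and circadian clock genes did not pass there. This setting was chosen after the data were seen and leaves 1 Myh11-Cre library.

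Nuclear oxidative phosphorylation genes fell (-0.24, 30 of 30 lower, adjusted p = 1.38e-05, and adjusted p = 0.641 with an estimated correlation), but not without Itga8-Cre 2 (0.262). Skeletal muscle markers (-1.48, 21 of 21 lower, adjusted p = 0.000421, and adjusted p = 0.641 with an estimated correlation) and myosin chains (-0.8, 19 of 21 lower, adjusted p = 0.00138, and adjusted p = 0.612 with an estimated correlation) fell, but not without Itga8-Cre 1 or Myh11-Cre 3 (up to 0.424 and 0.172). Cardiac muscle markers fell (-0.7, 14 of 14 lower, adjusted p = 0.000565, and adjusted p = 0.633 with an estimated correlation), but not without Itga8-Cre 1 (0.172). Lymphocyte markers rose (0.55, 17 of 21 higher, adjusted p = 0.000421, and adjusted p = 0.612 with an estimated correlation), but not without Itga8-Cre 3 (0.15). Fat cell markers (-0.32, 21 of 23 lower, adjusted p = 0.000906, and adjusted p = 0.641 with an estimated correlation) and brown fat markers (-0.19, 14 of 14 lower, adjusted p = 0.0392, and adjusted p = 0.7 with an estimated correlation) fell, but not without Itga8-Cre 2, Itga8-Cre 3 or Myh11-Cre 1 (up to 0.469 and 0.757), and for brown fat also not without Myh11-Cre 3. Estrogen receptor response genes fell (-0.2, 10 of 12 lower, adjusted p = 0.0249, and adjusted p = 0.612 with an estimated correlation), but not without Itga8-Cre 1 or Myh11-Cre 1 (up to 0.0555). Red blood cell genes fell (-0.79, 7 of 8 lower, adjusted p = 0.0279, and adjusted p = 0.641 with an estimated correlation), but not without Itga8-Cre 2, Itga8-Cre 3 or Myh11-Cre 2 (up to 0.88). With the brown fat score as covariate, brown fat markers (0.954), fat cell markers (0.176) and red blood cell genes (0.0966) did not pass. The score is the mean of the brown fat markers, so the outcome for that list was fixed in advance and carries no information. Without Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3 together, skeletal muscle, cardiac muscle, myosin and red blood cell lists turned to higher. Lymphocyte markers turned to lower. Of Myh11-Cre this leaves only Myh11-Cre 1, the library lowest in skeletal muscle markers. The turn of the muscle lists therefore followed from the choice of libraries.

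With an estimated correlation, 0 of the 15 lists were called in Itga8-Cre against Myh11-Cre, and the smallest adjusted p with an estimated correlation was 0.612. The other 15 lists did not pass (adjusted p from 0.0606 to 0.912). Other splits of the same 6 libraries called between 7 and 21 lists with the preset correlation, against 15 in the real split.

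Both Cre lines were compared with the same Wild Type libraries, so their fold changes are not independent. Genes called by DESeq2 in both comparisons numbered 15, all lower in both Cre lines. Independent lists would share 0.831, but that value leaves out the shared controls, and no simulated value was computed for DESeq2 calls. They were Irs2, Impdh1, Spry4, Mmd2, the phosphatase Dusp4, the growth factor Gdf5, the Wnt receptor Fzd5, the lactate receptor Hcar1, Myh10, Flvcr1, Cgref1, Map6, Dlc1, Gng7 and Gm42615. Dusp4 was at 23.7 ± 3.22 CPM in Itga8-Cre, 21.4 ± 4.78 CPM in Myh11-Cre and 60.5 ± 24.3 CPM in Wild Type. At an unadjusted p under 0.01 in both comparisons, 44 genes were lower in both, where simulated unchanged groups against shared controls gave 10.4 on average (range 4 to 19) and independent lists would share 3.05. Of genes higher in both there were 16, where these values were 20.2 and 1.09. The correlation of the fold changes across genes was 0.75 against 0.501 in the simulation, their covariance was 0.296 against 0.0984, and genes are not independent replicates. EdgeR called 0 genes in both comparisons.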

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

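The tests in this part were planned, except the settings with muscle scores as covariates and without the libraries poorest or richest in muscle transcripts, which were chosen only after the result was seen. The direct comparison of the Cre lines tests whether their effects differ, and 3 genes passed it when adjusted over their own list. These were Itga8 with a log2 fold change of -1.79 in Itga8-Cre against Myh11-Cre, Fopnl with -0.59 and Snx29 with 0.53. None of the 3 passed over all genes in edgeR (adjusted p = 0.521 for Itga8 and Fopnl), and DESeq2 called Fopnl alone of the 3 (adjusted p = 0.00844). The Fopnl call stood without each of the 9 libraries (adjusted p over the list alone up to 0.0208). The Itga8 call ended without any 1 Itga8-Cre library, without Myh11-Cre 2 and without Myh11-Cre 3 (up to 0.099), and its log2 fold change ran from -2.24 to -1.52 over the 9 fits. The Snx29 call ended in 8 of the 9 fits (up to 0.157).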

How the results depend on the processing

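Settings chosen only after the result was seen were smooth and skeletal muscle scores as covariates, edgeR without robust moderation, leaving out the 2 libraries poorest in muscle transcripts (Itga8-Cre 1 and Myh11-Cre 1), and leaving out the 3 richest in skeletal muscle transcripts (Itga8-Cre 3, Myh11-Cre 2 and Myh11-Cre 3). The other settings were planned. Contrasts are given as Itga8-Cre against Wild Type (first), Myh11-Cre against Wild Type (second) and Itga8-Cre against Myh11-Cre (last). With 3 mice per group and mixed tissue, many results below moved with single libraries. Where a call was lost, gained or turned, the cause was not tested.

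EdgeR called 0 genes in each contrast. DESeq2 called 30, 828 and 19, limma voom 0, 0 and 0. In the second contrast edgeR called 1 gene (Hccs) with no filter, 1 with the replicate block, 1 with the brown fat score and 284 without the 2 muscle-poor libraries, and in the last 1 with the brown fat score. Genes called in both Cre lines against Wild Type numbered 0, against 60 at an unadjusted p under 0.01 and 15 by DESeq2. Neighbours called around Myh11 numbered 0, against 2 by DESeq2.

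In the last contrast Itga8 (log2 fold change -1.79) was no longer called over the targeted genes with no filter (-1.82), the replicate block (-1.78), the skeletal muscle score (-1.39) and without the 3 muscle-rich libraries (-0.15). In the second it was -1.91 without these 3, a fit that leaves 1 Myh11-Cre library. Myh11 in the first was no longer called against a minimum change of 1.2-fold (-0.77). It was called in the second with the smooth muscle score (-0.56), and in the last without the 2 muscle-poor libraries (-0.65) and without Myh11-Cre 1 (-0.71). Without the 3 muscle-rich libraries it was -1.32 in the second. Over the 9 fits without 1 library, Itga8 ran from -2.38 to -1.42 in the first contrast, from -0.57 (without Wild Type 2) to 0.39 (without Wild Type 1) in the second and from -2.24 to -1.52 in the last. Myh11 ran from -0.87 to -0.64, from -0.6 to -0.09 and from -0.71 to -0.17. In the last contrast Myh11 turned to 0.09 with the smooth muscle score and to 0.56 without the 3 muscle-rich libraries. With the smooth muscle score, Itga8 was at -1.42 (SE 0.28) in the first contrast and -0.85 (SE 0.28) in the last.

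Camera with the preset correlation called 13, 13 and 15 lists, with an estimated correlation 0, 0 and 0, and fry called 0, 1 and 1. With the replicate block, the calls on matrix genes and endothelial markers in the first contrast (0.0621 for each) and on red blood cell genes in the second (0.0923) and last (0.086) ended. Calls kept in the same direction numbered 13, 12 and 13 with RLE size factors and 11, 11 and 12 with the brown fat score. They numbered 9, 10 and 9 with the smooth muscle score and 12, 9 and 12 with the skeletal muscle score. Without the 2 muscle-poor libraries, camera with the preset correlation called 20, 12 and 20 lists, of which 13, 9 and 14 were called in the same direction with all libraries. Without the 3 muscle-rich libraries, list counts are not given, since 1 Myh11-Cre library is left. That library is the lowest in skeletal muscle markers, so muscle lists had to turn in the second and last contrasts. The lists below turned direction, and adjusted p values, where given, are those after the turn. In the first contrast these were oxidative phosphorylation without Itga8-Cre 1 (0.0161), brown fat (0.0049) and fat cell markers (0.917) without Itga8-Cre 2, and matrix genes without Itga8-Cre 3 (0.898), without Wild Type 1 (0.577) and with the smooth muscle score (0.271). Myosin chains turned with the smooth muscle score (0.0347) and without the 2 muscle-poor libraries (0.0299), as did oxidative phosphorylation without these 2 (0.0123). Over the fits without 1 library, matrix genes ran from 5.18e-05 (without Wild Type 2) to 0.898, oxidative phosphorylation from 4.6e-08 (without Itga8-Cre 2) to 0.548 (without Wild Type 2), brown fat from 0.0049 to 0.921 (without Myh11-Cre 1) and fat cell markers from 1.49e-09 (without Itga8-Cre 1) to 0.917. Without the 3 muscle-rich libraries, matrix (0.711), cell cycle (0.995) and skeletal muscle (0.00534) turned.

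In the second contrast fat cell markers turned with the brown fat score (0.0498), and matrix genes without Myh11-Cre 1 (0.000779) and without the 2 muscle-poor libraries (0.00426). Skeletal muscle turned with its own score (0.419), which is no test, since the score is the mean of its members. Over the fits without 1 library, matrix genes ran from 0.000779 to 0.888 (without Itga8-Cre 2). Without the 3 muscle-rich libraries, contractile (1.51e-12), modulated smooth muscle (7.91e-05), myosin (0.000741), fibroblast (0.0138), macrophage (0.936), skeletal muscle (1.49e-13), cardiac muscle (0.76) and red blood cell (0.76) lists turned.

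In the last contrast brown fat turned without Itga8-Cre 2 (0.626), cell cycle without Itga8-Cre 3 (8.8e-06) and Myh11-Cre 3 (0.00429), and modulated smooth muscle without Myh11-Cre 2 (0.0296). Over the fits without 1 library, these ran from 0.000153 (without Myh11-Cre 2) to 0.757 for brown fat, from 8.8e-06 to 0.922 (without Wild Type 3) for cell cycle, and from 0.00225 (without Myh11-Cre 1) to 0.892 (without Myh11-Cre 3) for modulated smooth muscle. With the smooth muscle score matrix (0.0199), myosin (0.77) and skeletal muscle (0.00617) turned. Skeletal muscle turned also with its own score (0.706), which again is no test. Without the 3 muscle-rich libraries, contractile (0.00223), modulated smooth muscle (1.41e-12), matrix (1.01e-14), myosin (0.00772), TGF-beta and BMP (0.0213), cell cycle (1.45e-34), fibroblast (0.00694), lymphocyte (0.0109), skeletal muscle (1.29e-08), cardiac muscle (0.058) and red blood cell (0.566) lists turned.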

Other observations

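Chosen only after the result was seen were the tests of tissue scores on Hccs, Fopnl, Arhgap6 and Tlr7, the test of the X chromosome segment, the test of 1 Itga8 copy and the splits on edgeR counts. The tests of Itga8 against contractile genes, of correlations within groups, and of splits on DESeq2 and list counts were written beforehand.

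Hccs, Arhgap6, Tlr7 and Fopnl were higher in all 3 Myh11-Cre libraries than in any Wild Type library. The tissue test was first made on the median of the 4 genes and was parted into 2 pairs of genes after that result was seen. The 6 scores, each used alone as covariate, were of brown fat, smooth muscle, skeletal muscle, macrophages, lymphocytes and mesothelium. The nerve and glial score, whose list fell in Myh11-Cre, was not used. Over these 6 scores, the lowest log2 fold change of Fopnl was 0.6 (SE 0.19) and that of Hccs 1.29 (SE 0.06). Each was above its change without a covariate divided by 2 (0.38 and 0.71) by more than its SE, Fopnl only narrowly. For this pair that argues against different amounts of any 1 of these tissues as the whole cause, though only weakly for Fopnl. Nerve and other tissues stay open. The lowest of Arhgap6 was 0.49 (SE 0.37) and that of Tlr7 0.91 (SE 0.4). Neither was above its change without a covariate divided by 2 (0.41 and 0.64) by more than its SE. For Arhgap6 and Tlr7 the mix therefore cannot be told apart from genotype. An extra unbroken piece of the X chromosome from Tlr7 to Hccs is argued against by Msl3, which lies within it and had 0.1 (SE 0.09). An effect of the Myh11-Cre genotype stays open and was not tested, and reads of Arhgap6 and Hccs may be shared, since they overlap and the use of strand is not given in the sources used here.

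Itga8 was lower in all 3 Itga8-Cre libraries than in any Wild Type library. Fewer smooth muscle cells would lower Itga8 and contractile genes alike if all were read from these cells alone. The log2 ratio of Itga8 to 36 contractile genes was lower by a median of -1.49, which argues against fewer such cells as the whole cause. All 36 ratios share the Itga8 values of the same mice, so they are not separate evidence. Loss of 1 of 2 Itga8 copies is a candidate explanation, for which the log2 ratio to Acta2 was -1.03 (SE 0.11). This value depends on the reference gene and ran from -1.01 for Susd5 to -2.48 for Des. Against most contractile genes Itga8 was lower than against Acta2. Some contractile genes may carry signal of skeletal muscle tissue. Without the 2 muscle-poor libraries, 5 of the 36 were called higher in Myh11-Cre, beside 8 of 21 skeletal muscle markers. That setting left out libraries picked on muscle transcripts, so these calls cannot show whether contractile genes carry such signal. How far such signal moved the ratios was not tested. The labels give no copy number, so this and other effects of the Itga8-Cre genotype stay open.

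DESeq2 called 828 genes in Myh11-Cre against Wild Type, and tissue carried with the aorta in different amounts is a candidate explanation for many of them. Within groups, the 569 genes called lower, list members left out, had a median correlation of 0.84 with the nerve and glial score, where 95% of 1000 random sets of genes were below 0.09. The genes called higher had 0.47 with the mesothelial score (243 genes) and 0.63 with the skeletal muscle score (249 genes). For these, 95% of random sets were below 0.01 and 0.05. Both values come from 1 set of genes, with the members of each list left out, so they are not separate evidence. Genes that move together for any reason would exceed random sets, so this test does not single out carried tissue. Over the 9 libraries the most abundant mesothelial gene, Muc16, ranged from 22.2 to 137 CPM, and Acta1 of skeletal muscle from 4.57 to 3640 CPM. The most abundant nerve list gene, Scn7a, ranged only from 91.2 to 125 CPM, Dbh from 15.5 to 207 CPM, and of glial genes in Myh11-Cre Cdh19 fell by 0.54 when adjusted over the list alone (but not without Myh11-Cre 2, Myh11-Cre 3, Wild Type 2 or Wild Type 3, up to 0.0636) and Mbp had 0.14 and did not pass, so the part of glia stays open, and 0 of 21 nerve, 0 of 12 mesothelial and 7 of 21 skeletal muscle genes are in another list, and an effect of the genotype on these tissues stays open and was not tested.

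Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. Every split reaches a real count of 0, so the 10 given for edgeR was fixed in advance and carries no information. In Itga8-Cre against Wild Type, edgeR called 0 genes and at most 1 in another split (10 splits as large), DESeq2 30 and at most 302 (3), and camera 13 lists and at most 19 (3). In Myh11-Cre against Wild Type, edgeR called 0 and at most 0 (10), DESeq2 828 and at most 336 (1), and camera 13 lists and at most 18 (7). In Itga8-Cre against Myh11-Cre, edgeR called 0 and at most 308 (10), DESeq2 19 and at most 965 (7), and camera 15 lists and at most 21 (5). At an unadjusted p under 0.05 edgeR gave 1316, 3187 and 1840 genes, and other splits gave at most 2262, 2147 and 3002. Limma voom called 0, 0 and 0. In the first comparison the split of Itga8-Cre 1, Itga8-Cre 3 and Wild Type 1 gave the 302 DESeq2 calls, and the next highest other split gave 33. In the last comparison other splits gave up to 965. A structure of the samples other than genotype is possible and was not tested.

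Rag1 was at 0.629, 0.443 and 477 CPM in Itga8-Cre 1, 2 and 3, and Dntt at 0.829, 1.69 and 128 CPM. The other groups varied too. Rag1 ranged from 44.6 to 274 CPM in Myh11-Cre and from 16 to 130 CPM in Wild Type. Dntt ranged from 9.97 to 77.5 CPM and from 4.63 to 26.1 CPM. Genes lower in both Cre lines at an unadjusted p under 0.01 numbered 44, and since 3 controls cannot be divided between the comparisons, part of the excess over the 10.4 simulated with no real effects may come from the shared controls, with 15 such genes by DESeq2. Mid1-ps1, a pseudogene listed on the Y chromosome and chosen after its values were seen, had 16, 25 and 21 counts in Myh11-Cre, 0, 0 and 0 in Itga8-Cre, and 0, 2 and 2 in Wild Type.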
